A study of Mus musculus with 4 samples.

How the data were processed

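The data are single-cell RNA sequencing libraries of sorted CD4+ Foxp3GFP+ Treg cells from mouse liver and spleen, 1 library from 12-day and 1 from 7-week mice for each tissue. Per the labels' protocols, CD4+ cells were enriched on magnetic beads, GFP+ cells were sorted, and libraries were made with a 10x Genomics 5' kit that also enriches T cell receptor sequences, which were not analysed here. The stage label of the 7-week samples reads "aged"; they are called 7-week samples here. The labels do not say how many mice went into a library.

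The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 4.0.0 per the file headers, on the mouse build mm10 per the submitters' processing notes. Seurat 4.0.2 is also named in those notes, but the deposited counts are whole numbers with no normalisation. The annotation release is not given in the sources used here. Each matrix lists 32285 features and only barcodes with at least 500 UMIs. GENCODE vM21 on GRCm38 was used for positions, overlaps and transcript lengths, and 32158 features (99.6%) matched it by Ensembl identifier. Gene counts in this kind of data come from the 5' part of transcripts.

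Barcodes numbered 8055 in neonatal liver (32519356 UMIs), 7720 in neonatal spleen (33813594), 2608 in 7-week liver (7442185) and 6163 in 7-week spleen (20246352). Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which were 5668 (70.4%), 6178 (80.0%), 2424 (92.9%) and 6024 (97.7%) in that order. Scrublet was run in each library at an expected rate of 0.8% per 1000 cells. Its automatic threshold marked 0% of cells and so had not worked, and the cells with the highest scores were marked at the expected rate instead: 257, 305, 47 and 290 cells. This rule was chosen after the threshold was seen. Doublets of Treg cells with each other are not removed by such scores.

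All filtered cells were clustered together without batch integration: counts scaled to 10000 per cell, log-transformed, 2000 variable genes without receptor segments, ribosomal, mitochondrial, haemoglobin and sex-linked genes, 30 principal components, 15 neighbours, and Leiden clustering at resolution 1.0, which gave 19 clusters. With 1 library per group and no integration, a cluster mostly of 1 library may be that library and not a cell type. Clusters were named from 22 fixed sets of cell type markers. A marker counted as raised at 1.5-fold or more over the other cells and in at least 5% of the cluster's cells. A cluster took the "-like" name of the set with the most raised markers, if there were at least 3, with at least 1 of its markers and no other set ahead of it among the cluster's 10 leading genes, leaving aside the T cell and Treg sets. Equal numbers gave no name. These naming limits were set after the data were seen. Clusters with 2 or more markers of another lineage among those genes were removed, although some of their cells held T cell RNA, which took out 48 (0.847%), 204 (3.30%), 2 (0.0825%) and 47 (0.780%) cells in the order given above.

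The main cells were 5366, 5683, 2375 and 5688. Their UMIs were summed per library and expressed as counts per 1000000 UMIs (CPM). For each comparison the ratio of CPM was computed with its exact conditional binomial interval, and genes with at least 25 CPM in the higher library and a ratio of at least 2 were counted. There is 1 library per group, so cells were not used as replicates and no test between groups was made. At this depth the median distance from value to interval bound over the named genes was 4.75% of the CPM in neonatal liver, 4.91% in neonatal spleen, 10.6% in 7-week liver and 6.06% in 7-week spleen. A share of cells has its exact binomial interval.

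The comparisons, the 19 gene lists, the markers, the filters, the thresholds on genes and the rule for naming genes were fixed before the data were examined. The lists cover Treg identity, resting and recirculating cells, effector Treg cells, tissue repair, homing receptors and integrins, helper lineage regulators, cytokines and mediators, proliferation, immediate early and stress genes, TCR signal response, type I interferon response, recent thymic output, a fetal and neonatal program, MHC class I, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis, and survival and apoptosis. Some genes belong to more than 1 list. Members at 10 CPM or more in either library entered a list's median log2 ratio, which was placed among the medians of 10000 random lists of the same size drawn from the same deciles of mean expression. Random lists were drawn for the main setting only, and medians under the alternatives described below were set against that range.

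Named genes are, for each comparison, the 10 highest and 10 lowest ratios among genes with at least 25 CPM and 100 UMIs in the higher library, without receptor segments, ribosomal, mitochondrial, haemoglobin, sex-linked and unnamed genes. To these were added up to 4 members of each list with the largest log2 ratio in either direction, Foxp3, Il2ra, Ikzf2 and Cd4 as a check of the sort, and the 10 largest differences in each direction between the tissue ratios of the ages. Genes outside this rule were chosen after their values were seen: AY036118, Nkg7, Tmed7, Grsf1, further values of Asb2, Lag3, Egr2, Pdcd1, Ccr8 and H2-T23, and the marker genes of other cell types. Results of some single genes that met the rule are not reported here. Of 198 named genes, 7 overlap another coding gene on the same strand (Bcl2a1b, Ctla2a, Fdps, Gata3, Hivep3, Myadm and Ndufb9) and their counts are uncertain, and 36 overlap 1 on the other strand. For 29 of 349 values of named genes, the 10 highest cells held over 25% of the UMIs, and the median was 6.57%. Counts of close relatives (Hspa1a and Hspa1b, Ifit3 and Ifit3b, H2-Q6 and H2-Q7, Bcl2a1b and Bcl2a1d, the Gbp and Hist1 families) cannot be fully separated.

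Shares of cells with a UMI were compared after thinning each cell to a fixed number of UMIs. Because 32.3% of 7-week liver cells lay below 2000 UMIs, 1000 UMIs were used as fixed in advance, which left out 491, 252, 154 and 87 cells of neonatal liver, neonatal spleen, 7-week liver and 7-week spleen. Within a class, ratios were computed where each library held at least 100 cells. Genes were counted there only with at least 25 CPM and 100 UMIs in the class in the higher library. List medians within a class did not use this floor and cover the members measured in the whole libraries.

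The ratio and list steps were tested on simulated counts with known changes. For the comparison of 7-week liver with 7-week spleen, 90.6% of 53 genes simulated at 0.25-fold (among 4783 genes) came back within 0.25 log2 units, the lowest of all sizes and comparisons. The intervals covered the true value for 95.2%, 95.3%, 94.8% and 94.9% of genes for neonatal liver against spleen, 7-week liver against spleen, and the ages in liver and in spleen. Among simulated lists with no change, 3.5%, 5.0%, 5.0% and 8.0% lay outside the central 95% in these comparisons.

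Alternatives were TMM scaling (edgeR), totals without the most abundant gene classes, all barcodes, a stricter filter (1000 genes, 5% mitochondrial UMIs), doublets kept, Foxp3-positive cells only, cycling clusters left out, equal weight per cell, thinned cells, floors of 10 and 100 CPM, and other clustering resolutions (0.5 and 2.0). Added after seeing the data were leaving out a pair of clusters of low depth, leaving out a pair of clusters low in Foxp3, subtracting the trend with transcript length, counting the cycling markers in place of the proliferation list, and clustering without marker genes. For the age ratios with the same cluster weights, clusters with at least 30 cells in both libraries were used at the mean of their shares. Their intervals came from 200 resamplings of cells and cover the spread of cells within a library, not between libraries. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.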

Results

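Regulatory T (Treg) cells were profiled by single-cell RNA sequencing (10x Genomics 5' gene expression) from the liver and the spleen of mice at 12 days and at 7 weeks of age. The cells came from C57BL/6 mice in which Foxp3, the transcription factor that defines Treg cells, carries a GFP tag, and CD4+ Foxp3GFP+ cells were sorted. The series describes the 12-day mice as also carrying a Cre-dependent YFP reporter and does not give this genotype for the 7-week mice. There were 4 libraries, 1 for each age and tissue, so no difference has a replicate check and no p-value is given. The intervals given below are exact 95% intervals (Poisson for a sum of counts, conditional binomial for a ratio, Clopper-Pearson for a share) covering counting error only. A fixed gene list is called higher or lower where its median log2 ratio lay outside the central 95% of 10000 random lists of the same size matched on expression, as a description of these libraries.

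After filtering, the neonatal (12-day) liver library held 5366 cells with 29080901 UMIs and a median of 4415 UMIs per cell. The neonatal spleen library held 5683 cells with 30213395 UMIs and a median of 4534. The 7-week liver library was the smallest, with 2375 cells, 7120375 UMIs and a median of 2649. The 7-week spleen library held 5688 cells with 18774394 UMIs and a median of 2905. Depth per cell therefore differed between the ages more than between the tissues.

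The sort was visible in each library. Foxp3 (ENSMUSG00000039521; GRCm38 chromosome X, 7573644 to 7595245) stood at 439 counts per 1000000 UMIs (CPM) in neonatal liver, 410 in neonatal spleen, 458 in 7-week liver and 429 in 7-week spleen. Ikzf2, which encodes the Treg transcription factor Helios, lay between 398 and 485 CPM, and Cd4 between 140 and 200 CPM. Il2ra, the high-affinity IL-2 receptor chain, was lowest in neonatal liver at 132 CPM, against 192, 204 and 244 CPM in neonatal spleen, 7-week liver and 7-week spleen. A Foxp3 UMI was found in 73.4%, 69.8%, 59.8% and 63.1% of cells in the order neonatal liver, neonatal spleen, 7-week liver and 7-week spleen, and in 35.2%, 32.4%, 35.7% and 33.9% after each cell was thinned to 1000 UMIs. In the clusters led by markers of other lineages the share was 45.8% of 48 cells in neonatal liver (median 5681.5 UMIs), 48.5% of 204 in neonatal spleen (median 1583) and 48.9% of 47 in 7-week spleen (median 2729). Thinned, these shares were 16.7%, 21.3% and 11.4%. Those cells also held a Cd3e UMI in 58.3%, 75.0% and 76.6%, so T cell RNA was present in them. In the cluster led by Lyz2, which held 102 of these cells in neonatal spleen, 87.3% held a Cd3e UMI and 63.7% a Foxp3 UMI, against 95.9% and 69.8% of the main neonatal spleen cells, and 64.1% and 20.7% against 72.8% and 32.4% when thinned.

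Some other measurements moved with age or tissue. Xist, expressed from the inactive X chromosome of female cells, stood at 302 and 301 CPM in the neonatal libraries and at 128 and 151 CPM in the 7-week liver and spleen, while the Y-linked Ddx3y stood at 8.46 and 7.41 against 25.1 and 28.0 CPM. RNA typical of both sexes was thus present at each age, in different proportions. Haemoglobin RNA was highest in neonatal spleen (Hbb-bs 197 CPM, against 1.38 in neonatal liver, 0.140 in 7-week liver and 3.30 in 7-week spleen). Hepatocyte RNA was low, with Alb at 2.41 CPM in neonatal liver and 8.71 CPM in 7-week liver.

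The first comparison asked how Treg cells of the neonatal liver differed from those of the neonatal spleen. The neonatal liver library carried more RNA of the effector, cytokine and mediator, tissue repair, homing and proliferation lists, and less of the list of resting, recirculating cells. Gzmb (granzyme B) was 4.66-fold higher in the liver library [4.52 to 4.81], Ccl5 6.35-fold [6.19 to 6.51], and Cxcr6, a chemokine receptor of liver-resident lymphocytes, 6.81-fold [6.25 to 7.44]. Id3 (ENSMUSG00000007872; chromosome 4, 136143497 to 136145755), an inhibitor of E protein transcription factors, was 4.14-fold lower [3.97 to 4.33]. Of 4825 genes at 25 CPM or more in the higher library, 129 were at least 2-fold higher in liver and 45 at least 2-fold lower.

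Ccl3 (ENSMUSG00000000982; chromosome 11, 83647844 to 83649355) had the highest ratio, with 36.1 CPM in neonatal liver against 2.15 CPM in neonatal spleen (16.8-fold, [13.1 to 21.9]). Ccl4 (ENSMUSG00000018930; chromosome 11, 83662584 to 83664683) followed with 123 against 7.74 CPM (15.8-fold, [13.9 to 18.2]). Both values rested on few cells. The 10 highest cells held 57.6% of the Ccl3 UMIs and 67.4% of the Ccl4 UMIs of the liver library, and 89.2% and 91.0% of those of the spleen library. Without the 10 highest cells of each library the ratios were 66.1 and 57.5. Leaving them out removed a larger part of the spleen UMIs than of the liver UMIs, which raises a ratio. These values rest on few spleen UMIs and do not show a larger difference. A Ccl3 UMI was found in 209 of 5366 liver cells against 17 of 5683 spleen cells. Its log2 ratio was 4.07, and 3.34 in thinned cells. Ccl5 (ENSMUSG00000035042; chromosome 11, 83525778 to 83530518) was abundant, at 1509 against 238 CPM. These 3 genes encode chemokines. Gzmb (ENSMUSG00000015437; chromosome 14, 56258838 to 56262260) stood at 752 against 161 CPM.

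Among the fixed lists, 8 of the 19 measured effector Treg genes were at least 2-fold higher in neonatal liver and none was 2-fold lower. The list's median log2 ratio was 0.83, above each of the random lists. Il10, the suppressive cytokine, was 4.70-fold higher [4.11 to 5.38], Id2 3.57-fold, Fgl2 3.47-fold and Klrg1 2.56-fold. Of the cytokine and mediator genes, 6 of 10 were at least 2-fold higher (median log2 1.48), among them Ifng (5.56-fold) and Lgals3 (3.54-fold). The tissue repair list had 4 of 13 members at least 2-fold higher and each of the 13 above 0 (median 0.73), with Pparg 3.08-fold and Il1rl1, the IL-33 receptor, 2.47-fold higher. Of the 15 homing receptors, 4 were at least 2-fold higher and 1 lower (median 0.31), with Ccr2 at 3.35-fold and Cxcr3 at 2.67-fold. Among 6 helper lineage regulators (median 0.64), Tbx21, which encodes T-bet, was 3.40-fold higher.

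Each of the 26 proliferation genes was higher in neonatal liver, 12 of them at least 2-fold (median 0.96), including Ccna2 (2.69-fold) and Birc5 (2.45-fold). Glycolysis genes were also higher, with 15 of 15 above 0 at a median of 0.31, led by Tpi1 (1.78-fold) and Aldoa (1.56-fold). Interferon response genes had a median of 0.43, with 16 of 18 members above 0, of which Ly6a (3.69-fold) and Gbp7 (2.31-fold) passed 2-fold. Ly6a and Gbp7 were 1.54- and 1.21-fold higher within resting-like cells, 1.25- and 1.34-fold within effector-like cells, and 2.77- and 2.12-fold within cycling-like cells. The Gbp genes are close relatives and their counts are uncertain.

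The resting and recirculation list went the other way, with 13 of 14 members lower in neonatal liver and a median of -0.60. Bach2, a repressor that maintains resting cells, was 2.65-fold lower, Ly6c1 2.11-fold and Dapl1 2.08-fold. The log2 ratio of Dapl1 was -1.06, and -2.20 without a pair of clusters low in Foxp3. Genes of recent thymic output had a median of -0.53, with Itm2a 2.52-fold and Sox4 2.47-fold lower in liver. Bcl2, which protects resting lymphocytes from apoptosis, was 3.03-fold lower, Gpr83 3.31-fold and Lta 4.85-fold. Lad1 was 8.67-fold lower [7.22 to 10.5]. Ribosome biogenesis genes were lower in 14 of 14 (median -0.34), including Myc (1.62-fold).

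The remaining lists differed little. The Treg identity list had a median of 0.17, with Entpd1 2.5-fold higher and Gpr83 lower. With totals without abundant gene classes this median was 0.11, inside the range of the main setting. Those totals shift all ratios alike, so this does not show another place among random lists. Over all deposited barcodes the median was 0.15, also inside that range. The TCR signal list had a median of -0.19 with no member 2-fold in either direction, and -0.06 inside the random range with cycling cells left out. Medians lay within the central 95% of random lists for immediate early genes (0.11, with Dusp1 2.06-fold higher), MHC class I genes (0.19, but 0.26 and outside that range with cycling cells left out), oxidative phosphorylation (0.09), cholesterol synthesis (0.03) and survival genes (0.05). The 4 measured fetal and neonatal genes had a median of 0.00 at the 46.8 percentile, with Plagl1 3.04-fold lower in liver. Some of the named genes were low in the neonatal spleen library alone: Snx20 (ENSMUSG00000031662) stood at 127 CPM in neonatal liver and 132 CPM in 7-week spleen, but at 26.3 CPM in neonatal spleen.

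The next comparison asked the same question at 7 weeks, between the 7-week liver and spleen. The 7-week liver library had more RNA of the homing, helper regulator, cytokine and mediator, immediate early and interferon response lists, and less of the TCR signal list, than the 7-week spleen library, while members of the effector and tissue repair lists lay in both directions. Cxcr6 (ENSMUSG00000048521; chromosome 9, 123806475 to 123811760) was 6.63-fold higher [5.31 to 8.32], Ccr2 (ENSMUSG00000049103; chromosome 9, 124101950 to 124113557) 3.95-fold [3.55 to 4.39] and Il1rl1 (ENSMUSG00000026069; chromosome 1, 40429570 to 40465415) 4.21-fold [3.32 to 5.35]. Egr2 (ENSMUSG00000037868; chromosome 10, 67535475 to 67542188), a TCR-induced transcription factor, was 10.3-fold lower [6.98 to 15.9], a log2 ratio of -3.37 that was -4.09 in thinned cells. Without a pair of clusters low in Foxp3 the log2 ratio of Cxcr6 was 2.08 in place of 2.73. Of 4903 genes, 71 were at least 2-fold higher in liver and 26 at least 2-fold lower.

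Homing receptors had a median of 0.59, with 5 of 18 members at least 2-fold higher, including Itgae (2.66-fold), the integrin chain CD103, and Ccr10 (6.78-fold, 10.1 against 1.49 CPM). The log2 ratio of Ccr10 was 2.76, but 4.07 in thinned cells and 2.17 with cycling cells left out. Ccr8 was 2.2-fold lower. Each of the 6 helper lineage regulators was higher (median 0.71), led by Tbx21 (2.51-fold), Rora (2.49-fold) and Ahr (2.02-fold). The effector list was split, with 5 of 18 members at least 2-fold higher and 4 at least 2-fold lower around a median of 0.28, which came inside the random range in thinned cells (0.14). Fgl2 (3.32-fold) and Gzmb (3.15-fold) were higher in liver, whereas Pdcd1 (3.36-fold), Tnfrsf9 (3.07-fold) and Lag3 (2.69-fold) were lower. The tissue repair list was split likewise (3 of 13 at least 2-fold higher and 2 lower, median 0.46), with Penk 2.69-fold lower. Cytokines and mediators had a median of 0.93, with Lgals3 4.21-fold and Ifng 3.18-fold higher, although the log2 ratio of Ifng was 1.01 in place of 1.67 without the clusters low in Foxp3.

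Immediate early and stress genes had a median of 0.30, with Fos 2.83-fold [2.71 to 2.96] and Klf6 2.61-fold higher and Nr4a1 2.0-fold lower. The TCR signal list had a median of -0.32, with 11 of 15 members lower. All 22 interferon response genes were higher (median 0.59), of which Ifit3b reached 2.43-fold and Ifit3 1.99-fold. This pair is nearly identical in sequence, and 10 cells held 38.5% and 35.7% of their UMIs. Cxcl10, an interferon-induced chemokine, was 4.96-fold higher, with 53.8% of its UMIs in 10 cells, and 10 cells also held 54.2% of the Ccr10, 31.0% of the Lgals3, 28.9% of the Cxcr6, 33.3% of the Tbx21 and 32.0% of the Ifng UMIs. Of the Penk UMIs of the 7-week spleen library, 10 cells held 27.6%.

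The resting list was higher in 7-week liver, with 12 of 13 members above 0 and a median of 0.31, led by Klf2 (1.72-fold) and Ccr7 (1.41-fold), so its direction was opposite to that at 12 days. Among cells with a Foxp3 UMI its median was 0.17, inside the random range. Id3 was lower in liver at 7 weeks as well (2.80-fold, [2.59 to 3.03]). The proliferation list had a median of 0.51 with 6 of 21 members at least 2-fold higher, but 53.3% of the Ccna2 UMIs lay in 10 cells. With cells of cycling clusters left out, this median turned to -0.19.

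Recent thymic output genes (median -0.64, Hivep3 2.66-fold lower), Treg identity genes (-0.19, Izumo1r 2.04-fold lower), ribosome biogenesis genes (-0.35, Nop16 1.79-fold lower) and oxidative phosphorylation genes (-0.08) were lower in liver. Glycolysis genes (0.19, Tpi1 1.43-fold) were higher. With TMM scaling their median was 0.17, inside the random range of the main setting. That scaling shifts all ratios alike, so this does not show another place among random lists. In thinned cells the median was 0.13, also inside that range. MHC class I (0.18, but 0.21 and outside that range with a stricter cell filter), cholesterol synthesis (0.15, but 0.25 and outside it among cells with a Foxp3 UMI) and survival genes (0.02) lay within the central 95% of random lists, as did Arid3a, the 1 measured fetal gene (0.51).

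**Figure D1:**
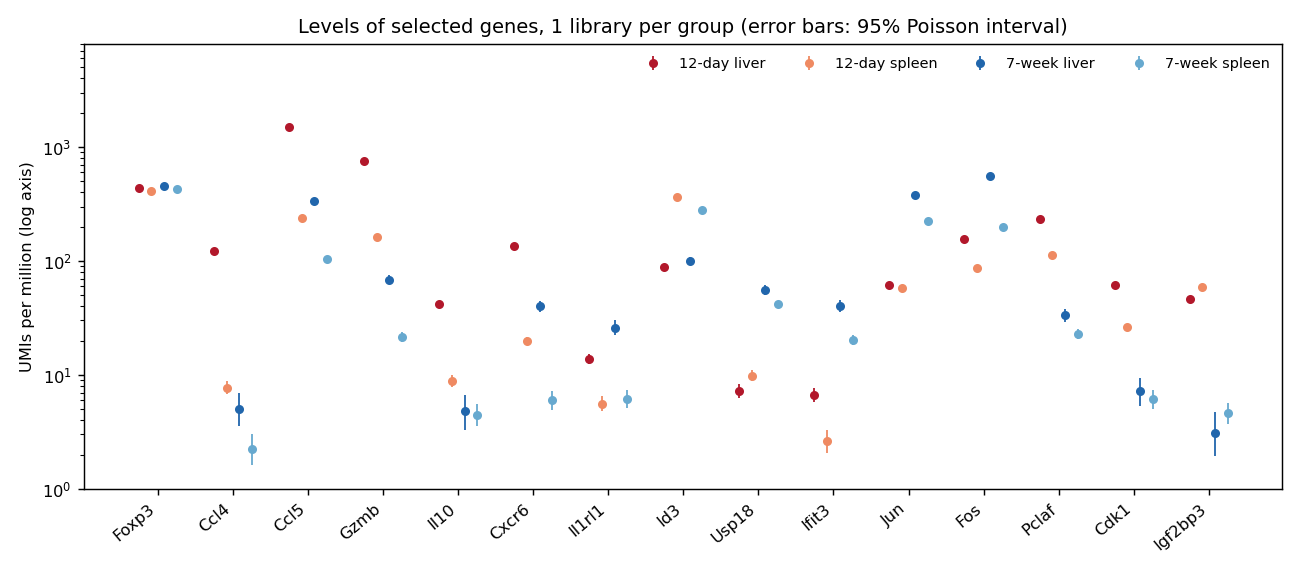
Expression in CPM (log axis) of selected named genes in the 4 libraries, with exact 95% Poisson intervals as error bars covering counting error only. Gzmb stood at 752 CPM in neonatal liver against 161 in neonatal spleen, 68.4 in 7-week liver and 21.7 in 7-week spleen, and Jun at 61.3, 57.6, 382 and 222 CPM in the same order.

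The tissue ratios of the ages share no library and could be set side by side. Across 5319 genes the log2 liver to spleen ratio at 12 days correlated with that at 7 weeks (Pearson r = 0.591, Spearman rho = 0.488), where genes are not independent replicates. Of the 200 genes at least 2-fold different at 12 days and the 127 at 7 weeks, 66 were shared. Of these, 52 were higher in liver at both ages, where independent lists would share 2.68, and 13 were lower at both, where independent lists would share 0.301. The gene that differed in direction was AY036118, a gene model without a functional name, singled out after its values were seen.

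**Figure D2:**
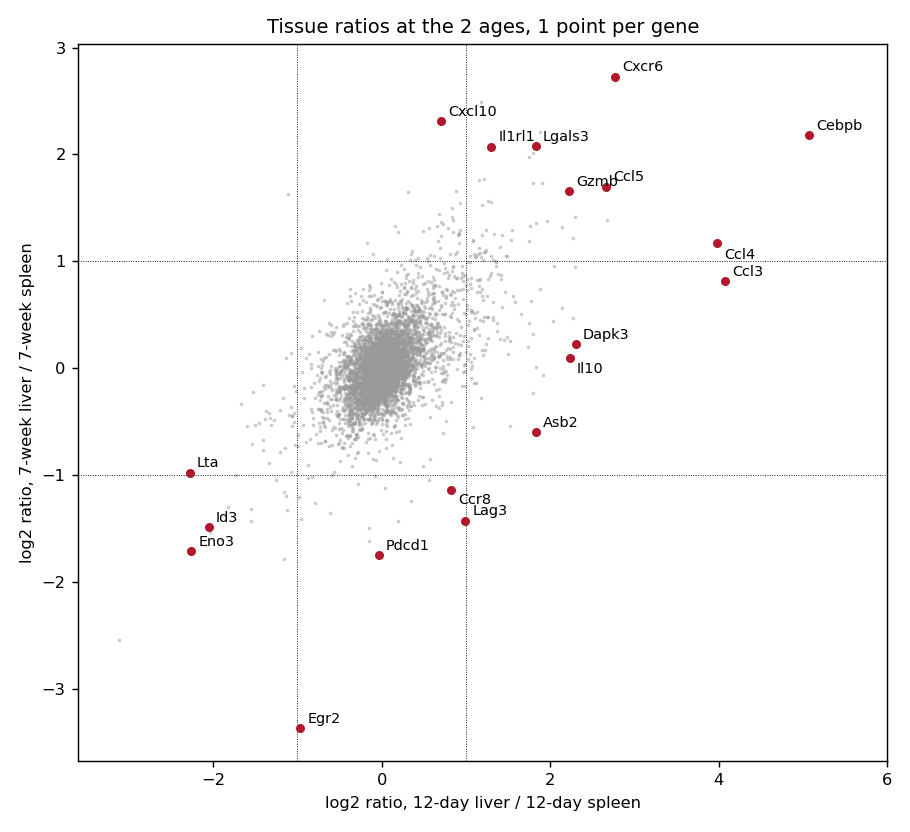
Each point is a gene, with its log2 liver to spleen ratio at 12 days on the x axis and at 7 weeks on the y axis, dotted lines at 2-fold and some named genes in red. Across 5319 genes r was 0.591, and 65 of the 66 genes 2-fold different at both ages lay in the same direction.

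Several genes had a larger tissue ratio at 12 days. Beside Ccl3 (16.8-fold at 12 days, 1.76-fold at 7 weeks) and Ccl4 (15.8 and 2.26), these included Il10 (4.70 and 1.07) and Cebpb (33.6 and 4.54), which stood at 17.8 CPM in neonatal liver and 0.530 CPM in neonatal spleen. Lag3 (ENSMUSG00000030124; chromosome 6, 124904361 to 124911705), an inhibitory receptor, was 1.98-fold higher in liver at 12 days and 2.69-fold lower at 7 weeks. Epcam had ratios of 2.88 and 0.687. In the other direction, Cxcl10 had ratios of 1.62 and 4.96, Gpr15, a receptor for gut homing, 1.24 and 3.13, and Myadm 2.27 and 5.61. Bach2 had ratios of 0.378 at 12 days and 0.897 at 7 weeks. These differences between ages were not tested.

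The age comparison within the liver asked what sets neonatal liver Treg cells apart from those of the 7-week liver. The neonatal liver library had more RNA of the proliferation, effector, and cytokine and mediator lists, and less of the interferon response, immediate early, resting and homing lists. Gzmb was 11-fold higher [10.1 to 12.1] and Igf2bp3, a fetal RNA-binding protein (ENSMUSG00000029814; chromosome 6, 49085223 to 49214957) 15-fold [9.85 to 24.0]. Oas1a (ENSMUSG00000052776; chromosome 5, 120896256 to 120907521), an antiviral enzyme induced by interferon, was 11.5-fold lower [9.45 to 14.0] and Jun (ENSMUSG00000052684; chromosome 4, 95049034 to 95052222) 6.23-fold lower [5.86 to 6.62]. Of 5088 genes, 246 were at least 2-fold higher in the neonatal liver library and 255 at least 2-fold lower.

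All 26 proliferation genes were higher, 20 of them at least 2-fold (median 1.91), with Cdk1 8.58-fold, Nusap1 8.51-fold and Pclaf 7.03-fold higher. With cells of cycling clusters left out, 162 in place of 246 genes were 2-fold higher, and the log2 ratio of Cdk1 was 1.42 in place of 3.10 and that of Nusap1 1.82 in place of 3.09. Of the effector genes, 8 of 19 were at least 2-fold higher (median 0.65), including Il10 (ENSMUSG00000016529; chromosome 1, 131019845 to 131024974) at 8.76-fold [6.23 to 12.7] and Klrg1 at 4.39-fold. Itgae was 5.73-fold lower. Cytokines and mediators (median 0.88) included Penk, an enkephalin precursor, at 8.60-fold higher, and Areg, a growth factor of tissue repair, at 4.01-fold lower. The tissue repair list as a whole had a median of -0.18, with Ccr8 6.61-fold and Pparg 4.91-fold higher. Ccl3 stood at 36.1 against 0.281 CPM (129-fold, [35.5 to 1063], from 2 UMIs in 7-week liver), a log2 ratio of 7.01 that was 4.64 in thinned cells. Fetal and neonatal genes had a median of 1.32 over 3 members, among them Cdkn1c (2.49-fold). Oxidative phosphorylation genes were higher in 19 of 19 (median 0.48, none 2-fold), with Ndufb9 1.65-fold and Sdhd 1.59-fold. Their median was 0.26 when the trend with transcript length was subtracted. No random range was drawn for the subtracted ratios, so its place among random lists is not known.

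Interferon response genes were lower in neonatal liver in 21 of 22, 15 of them at least 2-fold (median -1.30), including Oasl2 (9.16-fold), Usp18 (7.63-fold) and Ifit3 (6.02-fold). Gbp2b, an interferon-induced GTPase outside that list, was 24.6-fold lower [17.0 to 36.8]. Immediate early and stress genes had a median of -1.11, with 9 of 18 at least 2-fold lower, including Fos (3.58-fold). The heat shock genes Hspa1b (0.172 against 18.3 CPM, 106-fold) and Hspa1a (72.8-fold) are nearly identical and cannot be separated. In thinned cells their log2 ratios were -5.22 in place of -6.73 and -4.80 in place of -6.19. In the 7-week liver library 10 cells held 28.3% of the Oasl2, 35.7% of the Ifit3, 31.7% of the Gbp2b, 28.5% of the Hspa1b, 37.4% of the Hspa1a and 36.9% of the Areg UMIs. Resting genes were lower in 13 of 13 (median -0.91), such as Ly6c1 (4.80-fold) and Il7r (2.18-fold). Homing receptors were lower in 14 of 18 (median -0.71), led by Cxcr4 (8.08-fold). Cholesterol synthesis (median -0.56, Srebf2 1.86-fold lower, but -0.09 and inside the random range in thinned cells) and MHC class I genes (median -0.24, H2-T23 2.07-fold lower) were lower as well. The 6 helper regulators had a median of -0.49, and of -0.05 when the trend with transcript length was subtracted.

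TCR signal genes had a median of 0.08, with Tnfrsf9 3.47-fold and Tnfrsf4 2.36-fold higher and Cd69 2.40-fold lower. Medians within the central 95% of random lists were also found for Treg identity (-0.08, but -0.25 and outside among cells with a Foxp3 UMI), recent thymic output (0.11), glycolysis (0.31), ribosome biogenesis (0.29) and survival genes (-0.14, with Bcl2a1d 2.80-fold higher and Bcl2 2.39-fold lower). The recent thymic output median was 0.47 with the length trend subtracted, for which no random range was drawn.

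The spleen gave the same comparison of ages in a lymphoid organ. As in liver, proliferation and fetal genes were higher at 12 days, and interferon response and immediate early genes lower. Igf2bp3 was 12.7-fold higher [10.3 to 16.0], a log2 ratio of 3.67 that was 4.31 in thinned cells, Gzmb 7.44-fold [6.72 to 8.25] and Pclaf 4.92-fold. Oas1a was 11.4-fold lower [9.17 to 14.4] and Jun 3.86-fold lower [3.65 to 4.08]. Of 5003 genes, 107 were at least 2-fold higher in the neonatal spleen library and 122 at least 2-fold lower, and with cells of cycling clusters left out 65 were 2-fold higher.

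All 26 proliferation genes were higher in neonatal spleen (median 1.68, 18 at least 2-fold), as were all 4 fetal genes (median 1.22, Cdkn1c 2.94-fold). All 21 interferon response genes were lower (median -1.06, 11 at least 2-fold), including Ifit3 (7.72-fold) and Usp18 (4.22-fold). Immediate early genes were lower in 14 of 18 (median -0.85), with Dusp1 at 2.87-fold. Hspa1b (1 UMI in neonatal spleen, 369-fold, [65.5 to 14619]) and Hspa1a (2 UMIs, 178-fold) again cannot be separated, and their log2 ratios were -4.66 in place of -8.53 and -4.50 in place of -7.47 in thinned cells. The effector list had a median of -0.39 in spleen, opposite to liver, with Itgae 3.83-fold and Maf 2.05-fold lower and Klrg1 3.32-fold higher. Cytokines and mediators had a median of 0.93, with Lgals3 3.60-fold and Penk 2.81-fold higher.

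Treg identity (-0.30, Nt5e 2.47-fold and Lrrc32 2.11-fold lower), tissue repair (-0.32, Areg 4.18-fold lower), homing (-0.33, Cxcr4 7.52-fold lower, a log2 ratio of -2.91 that was -3.62 in thinned cells), cholesterol synthesis (-0.47, Hmgcs1 1.89-fold lower, but -0.24 and inside the random range in thinned cells) and MHC class I genes (-0.26, H2-Q6 2.31-fold and the similar H2-Q7 2.06-fold lower) were lower at 12 days. Medians inside the central 95% of random lists were found for resting genes (0.04, with Il7r 2.12-fold lower and Dapl1 2.40-fold higher), helper regulators (-0.17), TCR signal (-0.06), recent thymic output (-0.02, Itm2a 2.04-fold higher), glycolysis (0.14), oxidative phosphorylation (0.30), ribosome biogenesis (0.21) and survival genes (0.07, Mcl1 2.30-fold lower). Mcl1 was low in the neonatal spleen library alone, at 55.6 CPM. It stood at 119 CPM in neonatal liver, 116 in 7-week liver and 128 in 7-week spleen. Rln3 was 4.39-fold higher at 12 days, but it ends 339 bases upstream of Il27ra on the same strand and its counts are uncertain.

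Across 5319 genes the age ratios in liver and spleen correlated with r = 0.859 and rho = 0.849. All 243 genes at least 2-fold different in both tissues had the same direction, 139 higher at 12 days, where independent lists would share 7.77, and 104 lower, where independent lists would share 7.90. With cells of cycling clusters left out, 58 were higher and 98 lower in both tissues. Age moved together with Xist and Y-linked RNA and with depth per cell. The age ratios also followed transcript length, with a Spearman correlation of -0.396 in liver and -0.394 in spleen, against -0.018 and 0.135 for the tissue ratios at 12 days and 7 weeks. With that trend subtracted, 174 of the 246 genes higher and 167 of the 255 lower in neonatal liver stayed 2-fold, and 67 of the 107 higher and 86 of the 122 lower in neonatal spleen. Genes 2-fold higher in neonatal liver had a median transcript length of 1323.5 bases and those 2-fold lower 2933 bases.

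**Figure D3:**
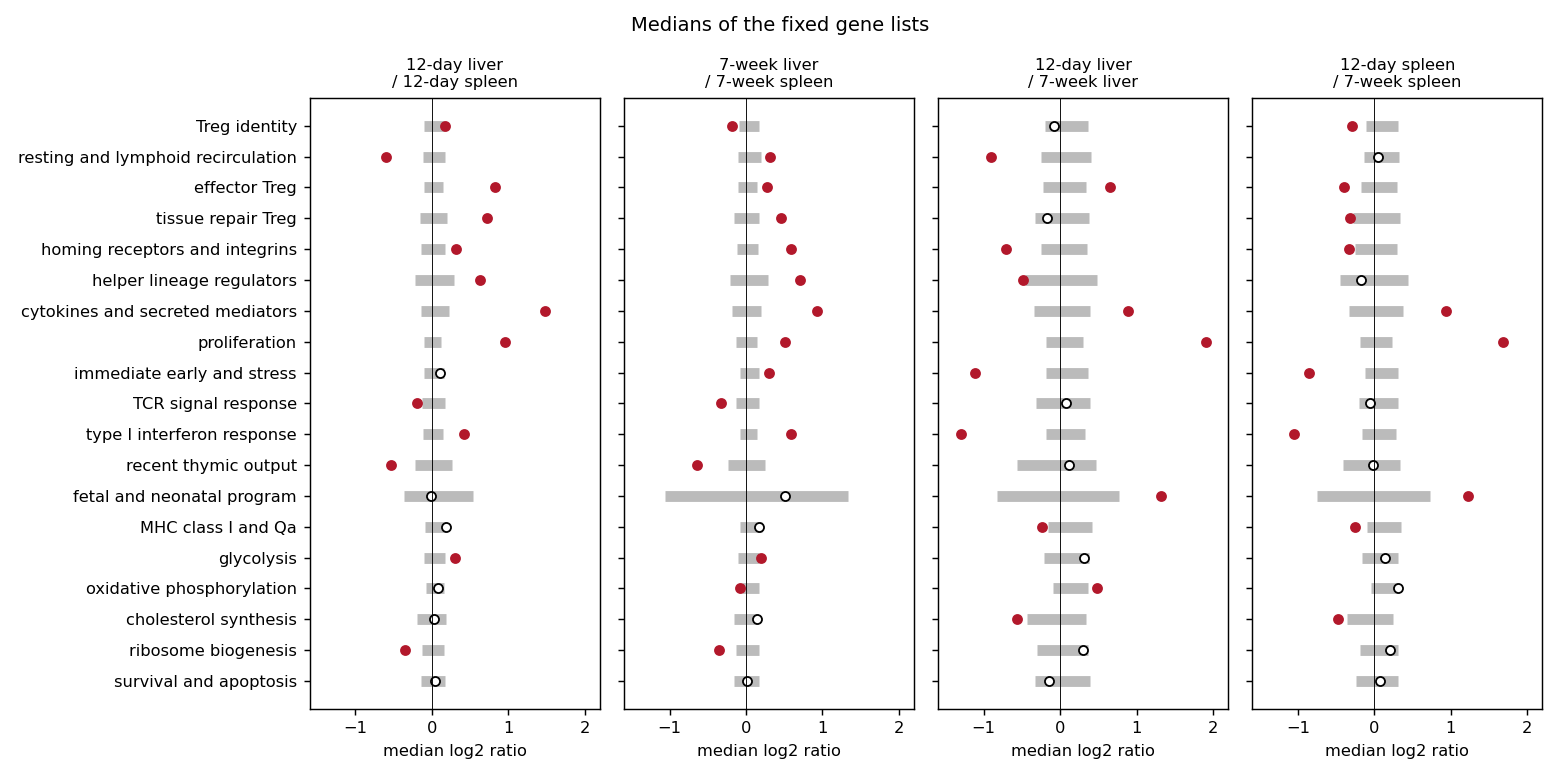
Median log2 ratio of each of the 19 gene lists in the 4 comparisons, with grey bars for the central 95% of random lists matched on expression and filled points outside it. Proliferation medians were 1.91 in liver and 1.68 in spleen for 12 days against 7 weeks, and interferon response medians -1.30 and -1.06.

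The cells were grouped into classes to describe how the populations were made up. Cycling-like cells made up 10.4% [9.58 to 11.2] of neonatal liver cells, 4.66% [4.13 to 5.24] of neonatal spleen, 2.69% [2.08 to 3.43] of 7-week liver and 1.05% [0.806 to 1.36] of 7-week spleen. Clustered without any marker gene, the shares were 10.2%, 4.55%, 3.20% and 0.966%, and at a clustering resolution of 2.0 they were 11.9%, 5.48%, 4.59% and 1.58%. An unnamed cluster of low depth with 8 raised cycling markers, none of them among its 10 leading genes, held a further 11.5%, 7.55%, 1.18% and 0.475% of the cells, so the shares depended on the naming rule. The share of thinned cells with 2 or more UMIs of the proliferation list was 49.1% [47.7 to 50.5], 46.6% [45.3 to 47.9], 40.3% [38.3 to 42.4] and 40.6% [39.3 to 41.9]. In resting-like cells it was 39.3%, 42.2%, 35.8% and 38.0%, so most of that share lay at a level also found outside cycling clusters.

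Resting-like cells, with RNA for lymphoid homing genes such as Ccr7, made up 16.0% [15 to 17.0] of neonatal liver cells, 44.6% [43.3 to 45.9] of neonatal spleen, 33.9% [32.0 to 35.9] of 7-week liver and 44.3% [43.0 to 45.6] of 7-week spleen. Without marker genes in the clustering these were 13.1%, 34.0%, 33.7% and 47.2%. At a clustering resolution of 2.0 they were 14.3%, 16.7%, 25.6% and 15.8%, so the order of the 7-week tissues was the opposite and the gap at 12 days was small. An unnamed cluster of low depth with 5 raised resting markers held 0.503%, 1.71%, 1.43% and 2.27%. Different clusters held this class at the ages: 1 cluster with 12.5% and 40.8% of the neonatal liver and spleen cells held 0.632% and 2.83% of the 7-week cells, and another with 33.2% and 41.2% of the 7-week cells held 0.894% and 2.02% of the neonatal cells. The third cluster of this class, low in Foxp3, held 2.53%, 1.78%, 0.126% and 0.264% of the cells of neonatal liver, neonatal spleen, 7-week liver and 7-week spleen. Interferon-like cells made up 1.10%, 0.686%, 5.85% [4.94 to 6.87] and 2.74% [2.33 to 3.20] in the order neonatal liver, neonatal spleen, 7-week liver and 7-week spleen, and 0.317%, 0.175%, 2.73% and 1.39% without marker genes. The libraries differed in depth per cell, and shares apply to cells inside the CD4 and Foxp3GFP gates.

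Effector-like cells made up 32.1% [30.9 to 33.4] of neonatal liver and 9.41% [8.67 to 10.2] of neonatal spleen cells, and 1.68% and 1.51% of the 7-week liver and spleen cells. The 7-week shares depended on which clusters took the name. Clustered without marker genes they were 43.2% and 20.1%, against 34.1% and 11.5% in neonatal liver and spleen. A cluster with raised effector markers that stayed unnamed held 0.839%, 0.510%, 44.0% and 21.0% of the cells of neonatal liver, neonatal spleen, 7-week liver and 7-week spleen. A further pair of such clusters held 1.14%, 9.15%, 2.86% and 20%, and 8.29%, 1.99%, 0.379% and 0.492%. No order of the ages can be read from this class, whereas the liver share exceeded the spleen share at 12 days in both clusterings. All unnamed clusters together held 40.4%, 40.7%, 55.8% and 50.4%.

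**Figure D4:**
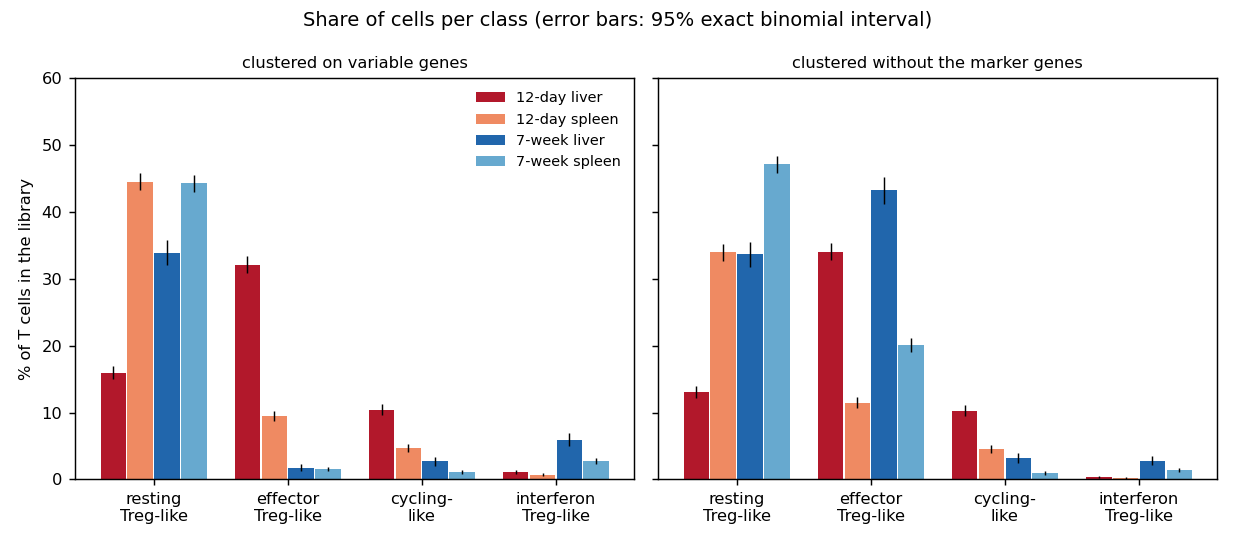
Share of cells (percent) per class and library, with exact 95% binomial intervals as error bars covering counting error only, clustered on all variable genes (left) and without marker genes (right). In the left panel resting-like cells made up 16.0% of neonatal liver and 44.6% of neonatal spleen cells, and cycling-like cells 10.4% and 4.66%.

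Within resting-like cells the tissue ratios of effector genes were smaller. Between neonatal liver and spleen, 46 genes were at least 2-fold higher and 22 lower among 857 and 2533 resting-like cells, and of 75 genes 2-fold different in the whole libraries 24 (32.0%) remained 2-fold and 64 kept their direction. The effector list had a median of -0.03 within this class against 0.83 in the whole libraries, and the proliferation list -0.03. Clusters were named from such markers, so the class leaves out clusters led by effector or cycling genes. The smaller ratios of these lists were therefore partly fixed in advance. Ccl5 was 1.69-fold higher [1.36 to 2.10] in liver against 6.35-fold in the whole libraries. Id3 remained 2.68-fold lower, and the homing list had a median of 0.35 with 9 of 15 members above 0. No random range was computed within the class. The resting list, which holds the genes that name the class, was higher in liver within it (median 0.59, 13 of 14 above 0), opposite to its direction in the whole libraries, and Fos was 3.05-fold higher. The tissues mixed the clusters of this class differently. The cluster low in Foxp3, led by Dapl1 and high in Ccr7, gave 136 of the 857 liver and 101 of the 2533 spleen cells. What this mix adds to the reversal was not tested. At 7 weeks 12 genes were higher and 11 lower between 806 and 2520 resting-like cells, and 12 of 34 (35.3%) remained 2-fold.

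Between the ages the interferon and immediate early differences were also present within resting-like cells, which different clusters held at the ages. Interferon response genes were lower at 12 days in 22 of 22 in liver (median -1.06) and 21 of 21 in spleen (median -0.85), and immediate early genes had medians of -0.71 and -0.76. Igf2bp3 was 12.4-fold higher in liver and 14.4-fold in spleen. In all, 105 genes were higher and 66 lower in neonatal liver, where 68 of 211 (32.2%) remained 2-fold, and 110 were higher and 92 lower in neonatal spleen, where 111 of 156 (71.2%) remained 2-fold. The proliferation list had medians of 0.05 in liver and 0.61 in spleen, in a class that leaves out the clusters named as cycling.

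Other classes held enough cells for some contrasts. Among effector-like cells, 35 genes were at least 2-fold higher in neonatal liver than in neonatal spleen and 1 lower (1723 and 535 cells), with 19 of 99 (19.2%) still 2-fold. There the homing list had a median of -0.24 with 6 of 15 above 0, the tissue repair list -0.03 and the interferon response list -0.15, all above 0 in the whole libraries. Among cycling-like cells 76 were higher and 39 lower (557 and 265 cells), with 82 of 146 (56.2%) still 2-fold. There the effector list had a median of 0.63 and the cytokine and mediator list 1.02, against 0.83 and 1.48 in the whole libraries. Among interferon-like cells of the 7-week libraries 33 were higher in liver and 3 lower (139 and 156 cells), with 12 of 20 (60%) still 2-fold. In that class the effector list had a median of 1.12 and the tissue repair list 1.33, against 0.28 and 0.46 in the whole libraries. The resting list had -0.51 there, against 0.31. These medians cover the 18, 13 and 13 members measured in the whole libraries, while only 676 genes passed the floor within the class. Members with few UMIs in these cells may weigh on them, and no interval was computed. A larger tissue difference in this class therefore cannot be read from them.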

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

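Of the tests in this part, the transcript length test was fixed before its result was seen and the others were chosen after it.

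Some genes differed with age in opposite directions in the tissues, among them the inhibitory receptors Lag3 and Pdcd1 and the TCR-induced Egr2. As log2 ratios of 12 days to 7 weeks in liver and in spleen, Lag3 had 1.62 and -0.79, Egr2 1.55 (2.87 in thinned cells) and -0.84, Asb2 1.53 and -0.89, and Pdcd1 1.06 and -0.65. The effector Treg list as a whole had medians of 0.65 and -0.39. As log2 ratios of liver to spleen at 12 days and at 7 weeks, Asb2 had 1.83 and -0.60, Lag3 0.99 and -1.43, Ccr8 0.83 and -1.14, H2-T23 -0.68 and 0.63, and the gene model AY036118 -1.12 and 1.63. The resting list had medians of -0.60 and 0.31 and the Treg identity list 0.17 and -0.19. These genes are among those lying at least 1.5-fold from equality in opposite directions. With 1 library per group, none of these differences was tested.

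Some clusters led by genes of other lineages were left out of the comparisons, except where all deposited barcodes were used. A cluster led by H2-Aa, Cd74 and Siglech held 0.194% of the filtered cells of neonatal liver, 1.60% of neonatal spleen and 0.232% of 7-week spleen. A cluster led by the B cell genes Cd79a and Ms4a1 held 0.547% of neonatal liver. A cluster led by the macrophage genes Lyz2 and C1qb held 0.106% of neonatal liver, 1.65% of neonatal spleen and 0.548% of 7-week spleen. In neonatal spleen 87.3% of the cells of the Lyz2 cluster held a Cd3e UMI and 63.7% a Foxp3 UMI, so T cell RNA was present in most of them. The shares are listed because they lie above the limit that a count of 0 allows, with no control sample, which does not tell how these cells came into the sort.

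The interferon response and immediate early lists were lower at 12 days than at 7 weeks in both tissues. The trend of the age ratios with transcript length was argued against as the whole cause, since after subtracting it the highest of the 4 list medians was still -0.67. With the same cluster weights at both ages, the immediate early list in liver had a median of -0.88 (interval -0.97 to -0.69). This argued against a different mix of the clusters used as the whole cause. Those 7 clusters held 57.0% of the neonatal and 93.6% of the 7-week liver cells. Several of them were mostly of 1 age. With doublets included, the cluster led by Gbp2b held 48 neonatal and 1085 7-week liver cells. The cluster led by Ly6c1 held 48 and 791, and that led by Gzmb 1825 and 40. In these the value rests on few cells of 1 age. A mix involving the clusters left out, some of them mostly of 1 age, was not tested and stays open. For that list in spleen the median was -0.59 (interval -0.75 to -0.46). The interferon list had -0.0606 in liver (interval -0.23 to 0.14) and -0.55 in spleen (interval -0.74 to -0.37). In these cases a different mix of clusters stays open, since the intervals reach above -0.5, and 1 cluster is named from interferon genes. The intervals come from resampled cells of 1 library per age. Sample preparation cannot be told apart from age, because each age and tissue has 1 library. The mix of sexes cannot either, since Xist and Y-linked RNA differed between the ages in both tissues. The YFP reporter genotype is given for the 12-day mice only, and any effect of it cannot be told apart from age. Age itself may underlie the pattern and stays open, untested.

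A set of 32 genes, among them Snx20, Dapk3, Cebpb, Tmed7, Grsf1 and Alyref, was at least 2-fold lower in the neonatal spleen library than in each other library. It also holds the interferon response genes Ifit3, Ly6a and Gbp7 and the interferon-inducible GTPases Gbp2b, Gbp6, Gbp10 and Iigp1. The interferon response list was lower at 12 days in both tissues and lower in spleen at both ages. These genes had the same directions, so their place in the set is not a separate result. GC content near the 5' end could affect capture and stays open, since the median GC of the set over the first 300 bases lay inside the central 95% of random sets (6.66 percentile), which does not exclude it. Another mix of cell classes remains possible for part of the set, since 50% of the genes (interval 31.9% to 68.1%) stayed 2-fold lower than in neonatal liver within resting-like cells. Snx20 differed 4.81-fold in the whole libraries and 4.26-, 4.58- and 3.99-fold within resting-like, effector-like and cycling-like cells, whereas Ly6a differed 3.69-fold and 1.54-, 1.25- and 2.77-fold. A property of the neonatal spleen at this age stays open, untested. An effect of that 1 library cannot be told apart from it.

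Ccl3, Ccl4, Ccl5, Gzmb and Nkg7 were higher in neonatal liver than in neonatal spleen. Cells without Foxp3 in the gate were argued against as the whole source. Among neonatal liver cells with 3 or more UMIs of such a gene, the lowest share with 3 or more Foxp3 UMIs was 38.6% (Ccl4, 32 of 83 cells, interval 28.1% to 49.9%). Among all 5366 main cells it was 38.5%, and in the clusters low in Foxp3 3.05% of 164 cells (interval 0.997% to 6.97%). Those clusters were chosen for low Foxp3 and had a median of 3874 UMIs. The cluster led by Ccl4 had a median of 7304 over all libraries, so the size of that gap cannot be read. Cells without Foxp3 as part of the source stay open. None of 4 macrophage genes exceeded 0.309 CPM in neonatal liver. At that level the RNA of the Lyz2 cluster, T cell RNA included, gave at most 0.0297% of the CPM of any of Ccl3, Ccl4, Ccl5, Gzmb and Nkg7. This argued against RNA of such macrophages as the source of Ccl5, Gzmb and Nkg7. For Ccl3 and Ccl4 it cannot decide, since the cluster held 0 and 3.17 CPM of them and 102 of its 143 cells came from neonatal spleen. Liver macrophages that express these chemokines were not modelled and stay open. These tests replaced earlier ones with less power: the log2 ratios among cells with a Foxp3 UMI (Ccl3 4.27, Ccl4 3.92, Ccl5 2.58, Gzmb 2.16, Nkg7 1.95) and the median log2 ratio of 7 macrophage markers (-0.68). A tissue difference in Treg cells may underlie these values as a hypothesis found and examined in the same data, and the tissue stays an untested explanation.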

How the results depend on the processing

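The alternatives were planned except for the cycling markers, the clustering without marker genes, the low-depth and low-Foxp3 clusters and the transcript length trend, which were chosen after the data were seen.

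Of 388 values of the main results under alternatives, 296 stayed within 1.5 times a count, 0.05 of a correlation or the interval of a share. List medians under alternatives were set against the random range of the main setting. That range was not redrawn, so a shift of all ratios alike could count as a move. Of 873 such medians, 840 kept their direction and their side of the range, 20 moved inside it, 12 moved outside it and 1 reversed. The proliferation median of 7-week liver against spleen reversed to -0.19 with cycling cells left out. This removes the clusters named as cycling, while other cells that express the list remain. Of 2090 values of named genes at least 2-fold different, 2031 remained 2-fold in the same direction and 0 reversed. Scaling, cell filter and doublet alternatives moved no count of genes over 1.5 times, except that totals without abundant gene classes gave 68 genes lower in neonatal liver than spleen, 201 lower in neonatal than 7-week spleen, and 21 in place of 13 lower in liver at both ages. With those totals more genes passed the floor and the ratios also shifted down. For the ages in spleen, 6102 in place of 5003 genes passed, and the median log2 ratio was -0.02 in place of 0.07. Lists with no member above the floor under an alternative have no value there. No paired analysis was possible because each group has 1 library and the labels pair no libraries. Counting error is largest in the 7-week liver library.

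With a floor of 10 CPM, which admits more genes, higher and lower counts were 242 and 81 for neonatal liver against spleen, 118 and 50 at 7 weeks, 441 and 421 for the ages in liver and 238 and 237 in spleen, and 425 genes shared a direction with age in both tissues. With a floor of 100 CPM, which admits fewer, they were 45 and 16, 24 and 12, 68 and 78, and 28 and 35, with 25 genes shared between tissue ratios and 65 between age ratios. With cycling cells left out, 162 genes were higher in neonatal liver and 65 in neonatal spleen than at 7 weeks, and 156 were shared, 58 higher and 98 lower at 12 days; removing those cells lowers their genes. The correlation of tissue ratios was 0.532 with equal weight per cell and 0.492 with thinned cells, and that of age ratios 0.788 with thinned cells, which hold fewer counts. Equal weight per cell gave 3 genes lower among effector-like cells at 12 days and 1 lower among interferon-like cells at 7 weeks. The cause was not tested.

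The following shares are in the order neonatal liver, neonatal spleen, 7-week liver and 7-week spleen unless named. Cells with proliferation UMIs were 77.0%, 75.8%, 73.7% and 73.6% at 1 UMI, 30.6%, 27.2%, 19.8% and 18.2% at 3 UMIs, and 92.2%, 90.7%, 79.2% and 83.4% without thinning, as more UMIs or a lower limit admit more cells. Counting cycling markers alone gave 12.7%, 5.87%, 3.24% and 1.32%, from a shorter list. Cycling-like cells were 12.2% of neonatal liver and 3.83% of 7-week liver with the stricter filter, and 12.2%, 5.72% and 3.59% of neonatal liver, neonatal spleen and 7-week liver among Foxp3-positive cells. Cycling cells hold more UMIs, so filters on depth keep more of them. At resolution 2.0 the cycling-like shares were 11.9%, 5.48%, 4.59% and 1.58%.

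Resting-like shares were 17.7%, 51.8%, 39.1% and 52.0% at resolution 0.5 and 14.3%, 16.7%, 25.6% and 15.8% at resolution 2.0. The stricter filter gave 47.3% in neonatal spleen, 28.4% in 7-week liver and 40.9% in 7-week spleen, and clustering without markers 13.1%, 34.0% and 47.2% in neonatal liver, neonatal spleen and 7-week spleen. Effector-like shares were 57.8%, 20.9%, 48.6% and 19.5% at resolution 0.5, and 34.1%, 11.5%, 43.2% and 20.1% without markers. At resolution 2.0 they were 30.5% and 11.8% in neonatal liver and spleen, and with the stricter filter 36.7%, 10.4% and 2.30% in neonatal liver, neonatal spleen and 7-week liver. Interferon-like shares were 0.336%, 0.264%, 2.40% and 1.42% at resolution 0.5, and 0.317%, 0.175%, 2.73% and 1.39% without markers. They were 0.951% in neonatal spleen and 4.55% in 7-week liver at resolution 2.0, and 6.89% in 7-week liver with the stricter filter. With other resolutions and without markers the shares follow which clusters took a class name. The stricter filter removes cells from classes that stay fixed. Beyond that the cause was not tested.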

Other observations

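The gene families in this part were assembled, and their values looked at, after the data were seen. Interferon-inducible GTPases, which act against intracellular microbes, were higher in liver than in spleen at both ages, with median log2 ratios of 0.80 at 12 days (15 of 16 above 0) and 0.68 at 7 weeks (17 of 17). At 12 days they were lower than at 7 weeks in all 17 measured members in liver (median -1.18) and all 17 in spleen (median -1.20), with 10 and 12 of them at least 2-fold lower. These genes form families of close relatives, so that counts of single members are uncertain. Gbp2b, Gbp6, Gbp7, Gbp10 and Iigp1 are also in the set lowest in the neonatal spleen library. Their liver to spleen ratios at 12 days were 4.90, 2.08, 2.31, 2.69 and 2.57 in the whole libraries. Within resting-like cells they were 3.61, 1.39, 1.21, 1.41 and 1.14. The 5 measured S100 calcium-binding protein genes were higher in liver at both ages (medians 1.23 and 0.95) and higher at 12 days in liver (0.69), with all 5 above 0 in each comparison. Between the ages in spleen their median was 0.33, inside the central 95% of random lists.

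Histone genes had a median of 0.86 between neonatal liver and neonatal spleen, with 43 of 44 above 0, and of 1.89 in liver and 1.48 in spleen between 12 days and 7 weeks, the same directions as the proliferation list. An unnamed cluster led by Hist1 genes, with 8 raised cycling markers, held 11.5%, 7.55%, 1.18% and 0.475% of the cells of neonatal liver, neonatal spleen, 7-week liver and 7-week spleen. Its median depth was 0.19, 0.26, 0.44 and 0.48 of the median of those libraries. Ligands of the TNF superfamily were lower in liver, with medians of -1.20 at 12 days (5 of 6 below 0) and -0.54 at 7 weeks (6 of 7 below 0). Heat shock genes as a family had medians of -0.06, -0.06, -0.17 and -0.14 for neonatal liver against spleen, 7-week liver against spleen, and the ages in liver and in spleen. The age medians lay below the central 95% of random lists, with 6 of 48 members at least 2-fold lower at 12 days in liver and 8 of 48 in spleen, and the tissue medians inside it. Chaperones of the endoplasmic reticulum had medians of 0.11, -0.13, 0.19 and -0.04 in the same order, all inside that range.

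More genes stood apart in neonatal liver than in any other library: 63 of 5202 genes were at least 2-fold higher there than in each other library, against 7 in neonatal spleen, 23 in 7-week liver and 2 in 7-week spleen. Many of the 63 are cell cycle or histone genes, such as Birc5, Ccna2, Cdk1, Mki67 and Hist1h1b. The count therefore partly repeats the higher share of cycling-like cells in that library. Genes at least 2-fold lower than in each other library numbered 14, 32, 12 and 30 in the same order. In the main cells, RNA of the immunoglobulin heavy chain gene Ighm was present at 565, 374, 477 and 366 CPM. The B cell gene Cd79a stood at 1.58 CPM or less there, but the cluster led by Cd79a had been removed. Over all barcodes Cd79a stood at 19.5, 3.55, 0.806 and 0.593 CPM. Cd79b, of the same marker set, stood at 29.50, 35.02, 30.76 and 24.98 CPM in the main cells. The source of the Ighm RNA was not tested.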
